A study of Homo sapiens with 4 samples.

How the data were processed

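MOLT-4 is a human T-cell acute lymphoblastic leukemia line. Total RNA was measured after 24 h in 4 conditions, namely no drug, romidepsin, tamoxifen, and both drugs together, with 1 Affymetrix expression array per condition. Labelled cRNA was made from 100 ng of total RNA, per the labels' protocols. Groups were taken from the treatment given in the labels, and the drug doses are not given in the sources used here.

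The deposited values are MAS5 signals, an intensity per probe set on a linear scale, per the submitters' processing notes. The software version is not given in the sources used here, and detection calls were not used here. The values of each array had a mean of 497 after trimming 2% at each end, so the scaling of the 4 arrays to a common trimmed mean had factors within rounding of 1. A microarray intensity has no read depth, and precision is limited by the number of arrays. Control probe sets for RNA quality and spike-ins were not analysed here, so the planned ratios for RNA quality were not computed. The share of probe sets above a floor is given, but that floor is the pooled median of the 4 arrays. The share is therefore no measure of RNA quality.

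Of 54613 probe sets, 41091 had a single gene symbol in the platform annotation, 1801 had several and 11721 had none. No gene was named from a probe set with several symbols. Gene identifiers of 41037 probe sets were matched to the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Signals were scaled first, then raised to a floor of 67.6, the median of all probe sets pooled over the 4 arrays, and then turned to log2. The probe set with the highest mean signal stood for a gene, leaving out probe sets marked by the manufacturer as open to cross-hybridisation where the gene had another. Of 19775 genes with a probe set, 12981 were above the floor on at least 1 array and are called measured, and 10291 were above it on all 4. A ratio against an array at the floor is a bound and is written as "at least". The other probe sets of a gene gave its technical range, which 9252 genes with a single probe set lack.

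Each comparison is a log2 ratio of 2 arrays, with the number of measured genes at least 2-fold higher and lower. Departure from additivity is the log2 ratio of the combination to romidepsin, minus that of tamoxifen to untreated. An array was said to stand alone for a gene where it lay at least 2-fold above or below each of the other 3 and these lay within 1.5-fold of each other. With 1 array per condition, no ratio has a replicate check, and no p-value was computed for the comparisons of 2 arrays. The layout does hold a pair of arrays with and without each drug at both levels of the other drug. An additive model, romidepsin plus tamoxifen, was therefore fitted with limma (lmFit and eBayes with a mean-variance trend) to all 4 arrays, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. This fit has 1 residual degree of freedom per gene, the disagreement between both pairs, moderated with 7.47 prior degrees of freedom. It tests a mean effect under additivity and says nothing of the combination itself. The residual holds any true departure from additivity together with noise, and the p-values weigh a mean effect against both. Nothing in the labels says that the arrays came from separate experiments, so that noise may be technical spread only.

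For gene lists, 40 lists (pathways, drug targets, and markers of cell types that a T-cell line would mostly lack) held 970 entries, of which 869 had a probe set. The median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on mean log2 signal in 20 bins. The excess is the list median minus the median of those random lists, and a list outside their central 95% lay below the 2.5th or above the 97.5th percentile. Such a percentile describes these arrays and is no test across samples. For the limma fit, p-values were also adjusted within each of the 40 lists alone, separately for each drug. No adjustment was made across lists or drugs, so calls over a list alone are weaker than calls over all genes. The lists, the comparisons and the rule for named genes were fixed before the data were examined, as were the alternatives except where stated. The rule took, for each treatment against untreated, the 8 largest increases and 8 largest decreases above the floor on both arrays and up to 4 bounds each way. For the other comparisons it took the 5 largest each way, and for each list described, the 2 highest and 2 lowest members. A ranked gene needed every other probe set of its own above the floor to move in the same direction. Symbols of unnamed loci, Y-linked genes and XIST were skipped. A fixed set of targets and response genes was always named where measured, apart from an item that is not reported here.

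The steps were tested on simulated data in which separate sets of genes carried known folds in each effect, with noise taken either from the departures from additivity or from the ratios of romidepsin to untreated. The first source holds any true departures and the second any true effect of romidepsin, which would add to the noise, but neither holds the spread between separate cultures, so whether they overstate or understate it is not known. With these sources 13518 and 13342 genes were tested. For the romidepsin effect, limma recovered 3 and 11 of 67 genes set at 1.5-fold, 33 and 36 of 67 at 2-fold, and 57 of 66 at 4-fold with either source. For the tamoxifen effect it recovered 6 and 18 of 67 at 1.5-fold, 38 and 41 of 67 at 2-fold, and 62 of 66 at 4-fold. Among genes simulated without a change, it called 0 of 13118 and 0 of 12942. For the combination against untreated, 38 of 67 genes set at 2-fold and 61 of 66 at 4-fold reached the 2-fold threshold with either source. A combination array set apart was found for 19 and 18 of 67 genes at 2-fold, and for 53 and 57 of 66 at 4-fold.

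Alternatives covered scaling to a common median, quantile normalization, scaling on 100 normalization control probe sets, floors at the 25th and 65th percentile, log2 of signal plus the floor value, the median over all probe sets of a gene, thresholds of 1.5-fold and 4-fold, and other settings of the limma fit. Restriction to genes with a mean signal above 500, and to genes above the floor on all arrays compared, was not planned and was added once the data had been examined. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.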

Results

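Gene expression was measured in MOLT-4 cells left untreated, exposed to romidepsin, an inhibitor of class I histone deacetylases, exposed to tamoxifen, a selective estrogen receptor modulator, or exposed to both drugs. The comparisons ask what each drug alone went with, what both together went with, and whether the combination array differed from the product of the single-drug folds. Each condition has 1 array. No difference between conditions therefore has a replicate check, and "higher" and "lower" describe these arrays.

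The median signal of all probe sets was 62.0 on the untreated, 64.6 on the romidepsin, 67.6 on the tamoxifen and 77.1 on the combination array. The share of probe sets above the floor was 48.5%, 49.2%, 50% and 52.4%, and the 99th percentile was 14970, 14937, 13853 and 13493. The combination array thus had a higher median and a lower 99th percentile than the others. Across genes, which are not independent replicates, the log2 signals of the untreated, romidepsin and tamoxifen arrays correlated at 0.989 to 0.990, and those of the combination array with these 3 at 0.955 to 0.970.

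Transcripts of the drug targets differed little between the arrays. HDAC1, the brightest of the 3 class I deacetylases named, had signals of 14698, 14397, 14686 and 15090 on the untreated, romidepsin, tamoxifen and combination arrays, and HDAC2 had 11359, 11681, 12585 and 10699. HDAC3 had 2682, 2675, 2179 and 3043 in that order. ESR1, which encodes estrogen receptor alpha, lay close to the floor at 49.6, 58.9, 73.0 and 72.1. ESR2, estrogen receptor beta, and ABCB1, a drug efflux pump, were not above the floor in the probe set used for them, although another probe set of ESR2, of a kind open to cross-hybridisation, reached 94.1. EBP, a sterol isomerase that binds tamoxifen, had 4995, 5067, 5832 and 3944. MYC had 9863, 10581, 8275 and 7665, and the survival gene BCL2 had 512, 497, 541 and 396. BCL2L11, which encodes the death-promoting protein BIM, had 1424, 1835, 1455 and 2376, but its probe sets differed in direction for each drug alone and for the combination against untreated. CDKN1A, the cyclin-dependent kinase inhibitor p21, had 265, 348, 376 and 627.

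Romidepsin was set against untreated to describe the histone deacetylase inhibitor alone. CSRP2, a LIM-domain protein, was 5.38-fold higher on the romidepsin array, with log2 ratios of 0.88 to 2.43 over its probe sets. NPTX2, a neuronal pentraxin, went from 329 to 1414, and ANXA1, the phospholipid-binding annexin A1, from 514 to 2148. The interferon-induced gene IFI44L was 4.15-fold higher, the Polycomb component PCGF2 4.02-fold, SMCO4 3.88-fold, the proton-sensing receptor GPR65 3.74-fold and ANXA3 3.40-fold. Genes at the floor without drug were at least 4.69-fold higher for CAVIN1, a coat protein of caveolae, at least 4.59-fold for CCND2, which encodes cyclin D2, at least 3.98-fold for KLHL25 and at least 3.78-fold for TNNT1.

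Among genes lower with romidepsin, TSNARE1 went from 264 to 87.3, LINC01134 from 200.4 to 76.5 and GAS6, a ligand of TAM-family receptor kinases, from 282 to 129. YWHAH-AS1, SPRR4, LINC01231, RUSC2 and PRSS58 had log2 ratios between -1.21 and -1.12. TAMALIN was at least 3.81-fold lower, EEF2KMT at least 3.18-fold, PODNL1 at least 2.71-fold and SEC16B at least 2.56-fold.

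Among the fixed lists, thymocyte and T-ALL transcription factors lay above matched lists with romidepsin by 0.17 log2 (percentile 99.99 of 10000 random lists). Of 20 measured members 18 were higher, none by 2-fold, led by ID3 at 0.84 and HHEX at no less than 0.73, while TCF3 was at -0.17, and the probe sets of HHEX and TCF3 differed in direction. Genes of the T-cell receptor and its signalling lay 0.15 above matched lists, with CD28 and CD2 at no less than 1.1 and 0.98 and with PTPN6 and CD8B at -0.57 and -0.93. When romidepsin was added to tamoxifen this list was not raised (percentile 10.2). Interferon response genes lay 0.17 above (percentile 98.7), with IFI44 at 0.87 beside IFI44L, but XAF1 at -0.85, with probe sets in both directions, and IFITM2 at -0.50. Glycolysis and hypoxia genes lay 0.12 above (percentile 99.8), with ADM at no less than 1.39, HK1 at 0.53, SLC2A1 at -0.28 and ANKRD37 at -0.37. G2/M genes were lower in 30 of 36 members (excess -0.08, percentile 0.03) and G1/S genes in 28 of 35 (excess -0.08, percentile 0.13), in both lists without a member 2-fold lower. The list of genes commonly higher after deacetylase inhibitors lay at percentile 67.1, with GADD45B at 0.65 and CITED2 at 0.44 highest and TP53INP1 at -0.39 lowest, and none of its 18 measured members differed by 2-fold.

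In all, 181 genes were at least 2-fold higher and 49 lower with romidepsin, against 159 and 73 after scaling to a common median. Among genes simulated without a change, 210 and 161 passed 2-fold in either direction, with noise from the departures and from the romidepsin ratios. The noise behind both counts was taken from differences that include these arrays, so the counts do not tell how many of the genes are noise. A second probe set passed 1.5-fold in the same direction for 21 of 75 higher genes that had one (28%, against 4.92% of all genes) and for 0 of 15 lower genes (against 2.88%).

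**Figure D1:**
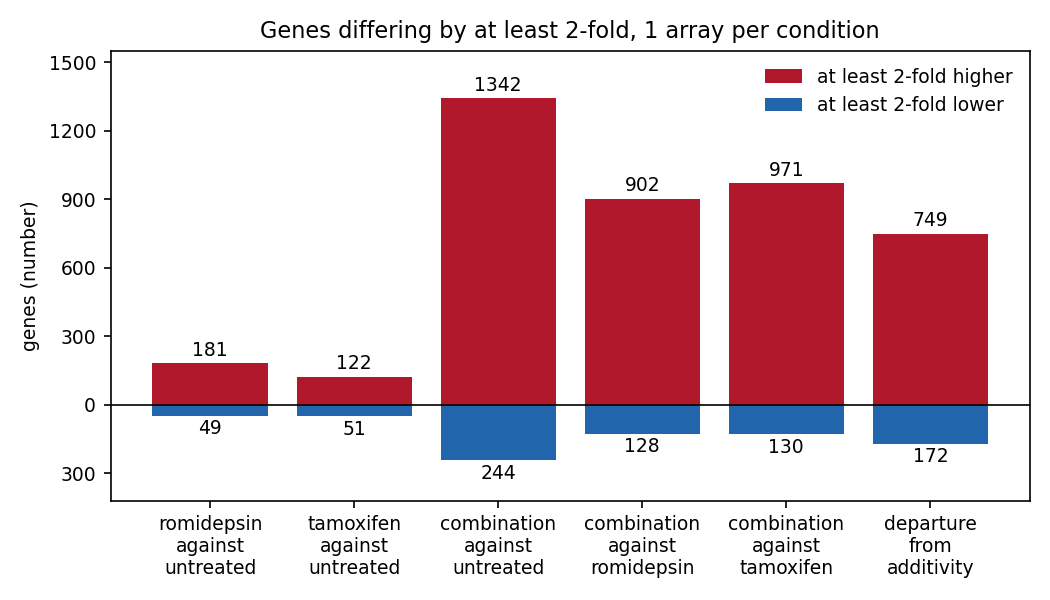
Number of measured genes at least 2-fold higher or lower in each of the 6 comparisons, counted from single arrays. The bars for the combination against untreated reach 1342 higher and 244 lower, while romidepsin reaches 181 and 49 and tamoxifen 122 and 51.

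Tamoxifen alone was marked by lower signals of genes that export cholesterol. ABCA1, a cholesterol efflux pump, went from 1868 on the untreated to 68.7 on the tamoxifen array, 27.2-fold lower and only just above the floor. Its log2 ratio was -4.77, and -4.48 or lower in another probe set that was at the floor on the tamoxifen array. ABCG1, a related transporter, went from 4880 to 1952, and MYLIP, a ubiquitin ligase, from 450.3 to 122. These 3 genes are targets of the sterol-sensing receptor LXR, and all 10 of their probe sets above the floor on the untreated array were at least 2-fold lower. The list of cholesterol efflux and LXR targets, with 7 measured members, lay 0.49 below matched lists, lower than all 10000 random lists. Genes of cholesterol synthesis and uptake lay 0.25 above matched lists, higher than all random lists, and 21 of 27 were higher, with the sterol reductase TM7SF2 at 1.16 and HMGCS1, which makes the mevalonate precursor, going from 4336 to 8951, while PMVK was at -0.27 and ACACA, a fatty acid synthesis gene in the list, was the lowest.

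ASS1, the arginine-synthesis enzyme argininosuccinate synthase, was 8.65-fold higher with tamoxifen, from 186 to 1610. ZNF117 was 4.09-fold higher, with log2 ratios from 0.35 to 2.03 over its probe sets, and TM6SF1 was 3.68-fold higher. LRP11, MGC70870, STX17-DT, RAB9B and the HMG-box gene TOX2 were between 3.01-fold and 3.36-fold higher. NDST1 was at least 3.73-fold, KLHL25 at least 3.27-fold, SHPK at least 2.96-fold and ATOH8 at least 2.93-fold higher. In the other direction, the tyrosine kinase SRC and the oxysterol-binding OSBP2 were both 3.42-fold lower, DTX1, a regulator of NOTCH, 3.01-fold, the glycolysis regulator PFKFB4 2.79-fold and the receptor GPR17 2.52-fold. FGD2 was at least 4.92-fold lower, AK4 at least 3.55-fold, EEF2KMT at least 3.18-fold and SIK1 at least 2.71-fold.

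Of the other lists, glycolysis and hypoxia genes lay 0.28 below matched lists with tamoxifen, lower than all random lists, where they lay above with romidepsin. Among 26 members 19 were lower, with ANKRD37 at -0.89 beside PFKFB4, against VEGFA at 0.48 and SLC2A3 at 0.45. MYC and ribosome biogenesis genes were lower in 22 of 25 members (excess -0.22), with RRP12 at -0.99, again with probe sets in both directions, PES1 at -0.72 and the MYC antagonist MXD1 at 0.83. G2/M genes were lower in 29 of 36 (excess -0.12, percentile 0.19), with CDC20 at -0.58, PLK1 at -0.50, ANLN at 0.28 and ECT2 at 0.17. Oxidative phosphorylation genes were lower in 25 of 28 (excess -0.12, percentile 0.35), but lay at percentile 31.5 when tamoxifen was added to romidepsin. Amino acid and ER stress genes lay 0.16 above matched lists (percentile 99.6, outside the central 95% under 7 of 8 alternatives), with CEBPB at 1.15, the cystine transporter SLC7A11 at 0.97, DDIT4 at -0.25 and SDF2L1 at -0.32. Thymocyte and T-ALL transcription factors lay 0.27 above, with LMO2 at 0.90, TOX at 0.60, IKZF3 at -0.20 and ID1 at -0.43, and T-cell receptor genes lay 0.19 above, with PTPRC at 0.97 and CD8B at -0.72. The ratios of each single drug share the untreated array. When tamoxifen was added to romidepsin, T-cell receptor genes lay at percentile 48.7, and their departure from additivity had an excess of -0.18 (percentile 1.15). Estrogen receptors and targets lay at percentile 80.8, without any of 13 measured members 2-fold apart.

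With tamoxifen 122 genes were at least 2-fold higher and 51 lower. A second probe set passed 1.5-fold in the same direction for 17 of 50 higher genes that had one (34%, against 7.04% of all genes). Among lower genes it did so for 5 of 19 (26.3%, against 2.88%). The split of higher and lower genes was 84 and 83 after scaling to a common median, 80 and 74 after quantile normalization and 163 and 38 after scaling on control probe sets. Among genes simulated without a change, 207 and 140 passed 2-fold in either direction, with noise from the departures and from the romidepsin ratios. With noise from the departures this is 1.60% of the simulated genes, above the 1.33% of measured genes observed. That noise is therefore too large for this pair of arrays. Whether the noise from the romidepsin ratios is too large or too small is not known. Neither source holds the spread between separate cultures, so these totals do not tell how many genes are noise.

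**Figure D2:**
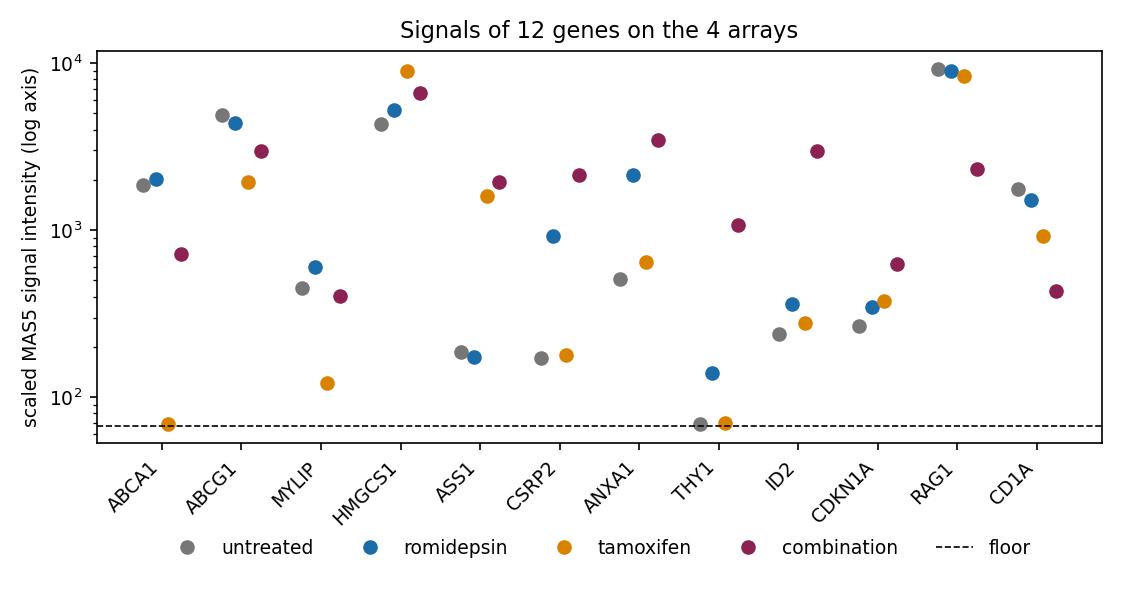
Signal (arbitrary intensity units, log axis) of 12 genes on the untreated, romidepsin, tamoxifen and combination arrays, 1 point per array, with the floor of 67.6 dashed. ABCA1 has 68.7 on the tamoxifen array against 1868 on the untreated array, and THY1 has 1077 on the combination array against 69.3 on the untreated array.

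The combination was set against untreated to describe both drugs together. LRP11 went from 76.0 to 1199, THY1, a surface glycoprotein of thymocytes, neurons and fibroblasts, from 69.3 to 1077 and BCL6, a transcriptional repressor, from 94.3 to 1354. TOX2 was 14.0-fold higher, NPTX2 13.1-fold, ID2, an inhibitor of E-protein transcription factors, 12.4-fold, CSRP2 12.3-fold and the imprinted gene PEG10 11.6-fold. From the floor, the kinase HIPK2 was at least 20.6-fold higher, CAVIN1 at least 17.6-fold, the NOTCH ligand DLL1 at least 15-fold and TMEM255A at least 14.5-fold. Probe sets of HIPK2 spanned log2 ratios from 0.30 to no less than 4.36.

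Lower on the combination array were LCT-AS1, 5.91-fold, and LCT, the gene of lactase in which it lies, 4.0-fold. The myosin MYO7B was 5.25-fold lower, the mitochondrial ribosomal protein MRPL54 4.48-fold, IFTAP 4.47-fold, DNLZ 4.19-fold and PPCDC, an enzyme of coenzyme A synthesis, 3.91-fold. CD1A, a surface marker of cortical thymocytes, went from 1759 to 433. ZBTB3 was at least 3.36-fold, GPR17 at least 3.34-fold, EPHX4 at least 3.15-fold and KMT5C at least 3.11-fold lower.

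Cell cycle genes were lower together on the combination array. Of 36 measured G2/M genes 35 were lower, 6 by at least 2-fold, and the list lay 0.53 below matched lists, lower than all random lists. CCNB1, which encodes cyclin B1, went from 9522 to 4140 and the proliferation marker MKI67 from 4123 to 1780, while CDK1 had a log2 ratio of 0.03 and probe sets in both directions. G1/S genes were lower in 31 of 35 (excess -0.35), with the phosphatase CDC25A at -1.40 and the replication factor CDC45 at -1.0, against CCND2 at no less than 3.44. Of the 5 measured CDK inhibitors 3 were at least 2-fold higher, CDKN1A among them at 1.24, although the list stayed outside the central 95% under only 5 of 8 alternatives. MYC and ribosome biogenesis genes were lower in 20 of 25, 5 by at least 2-fold (excess -0.42), with RRP12 at -1.08 and CAD at -1.04, while the MYC antagonists MXD1 and MXI1 were at 1.31 and 0.93.

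The list of genes commonly higher after deacetylase inhibitors lay 0.62 above matched lists on the combination array, higher than all random lists, with 8 of 18 members at least 2-fold higher. TP53INP1, a p53 target, was at 2.62 and GSN, which encodes gelsolin, at no less than 2.59, but TUBB3, whose probe sets differed in direction, was at -0.86 and KLF6 at -0.67. Fibroblast and cytoskeleton genes lay 0.92 above, and at the lowest 0.30 under the alternatives, with 8 of 15 at least 2-fold higher, among them THY1 and COL1A1, a collagen gene at no less than 3.45 whose probe sets differed in direction. Thymocyte and T-ALL transcription factors lay 0.71 above (lowest 0.39), with ID2 and ID3 (1.57) highest and TCF3 (-0.51, probe sets in both directions) and TAL1 (-0.45) lowest. Lysosome and autophagy genes were higher in 21 of 25 (excess 0.39), with WIPI1 at 2.34, their regulator TFEB at 1.96, HEXA at -0.28, whose probe sets differed in direction, and ATG7 at -0.58.

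In the NOTCH pathway 8 of 17 members were at least 2-fold higher and the list lay 0.57 above matched lists, with HEY1 at no less than 2.43 beside DLL1, while DTX1 was at -1.40 and the receptor NOTCH1 at -0.91. Genes of antigen presentation lay 0.54 above (lowest 0.23 under the alternatives), although only 9 of 16 were higher and 7 were lower. HLA-DMA was at 2.42, HLA-E at 1.91, HLA-DRB1 at -0.47 and the immunoproteasome subunit PSMB10 at -1.30. Neuronal genes lay 0.39 above (percentile 99.45), with MAPT, which encodes tau, at 2.81, NCAM1 at no less than 2.45, NEFH at -0.04 and TUBB3 at -0.86. DNA repair genes were lower in 21 of 25 (excess -0.27, percentile 0.82). Each of these 4 lists stayed outside the central 95% under 7 of 8 alternatives. Thymocyte surface and recombination genes went both ways, 6 of 22 at least 2-fold higher and 4 lower. CD69 was at 2.13 and the receptor KIT at no less than 2.78, while the recombinase gene RAG1 went from 9277 to 2334 beside CD1A, although its probe sets differed in direction. Pro-apoptotic genes lay 0.27 above, with BIK at no less than 2.5, BMF at no less than 2.38, BNIP3 at -0.64 and BID at -0.68, but their excess was -0.02 with the median over the probe sets of a gene.

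On the combination array 1342 genes were at least 2-fold higher and 244 lower than untreated. Among genes simulated without a change, 194 and 131 passed in either direction, with noise from the departures and from the romidepsin ratios. A second probe set passed 1.5-fold in the same direction for 445 of 648 higher genes (68.7%, against 18.5% of all genes) and 65 of 112 lower genes (58.0%, against 9.98%). Of the higher genes 703 (52.4%) and of the lower genes 163 (66.8%) lay within 1.5-fold of untreated on both single-drug arrays. Scaling to a common median gave 855 higher and 827 lower, and quantile normalization gave 1015 and 415, so the balance of directions is not fixed by these data.

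**Figure D3:**
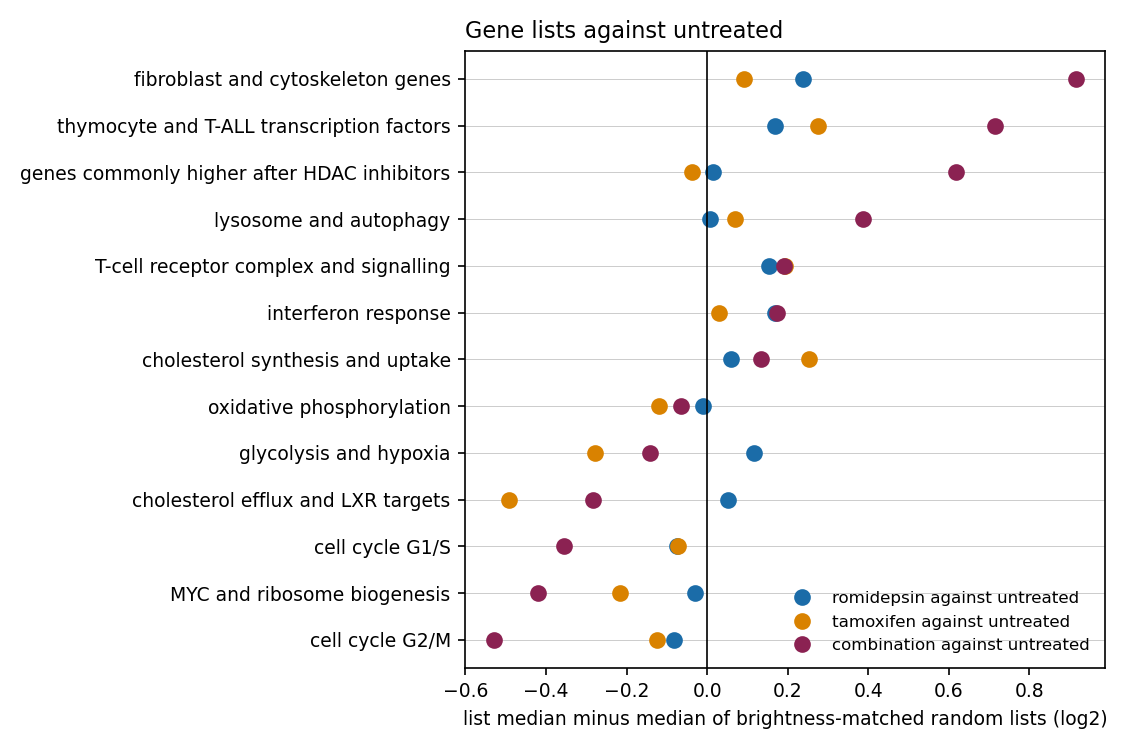
Excess of the median log2 ratio of 13 gene lists over matched random lists, for romidepsin, tamoxifen and the combination against untreated, 1 point per comparison. G2/M genes lie at -0.53 and fibroblast and cytoskeleton genes at 0.92 for the combination.

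The combination was next set against romidepsin, to describe tamoxifen added to romidepsin. ASS1 was 11.2-fold higher, DLL1 9.98-fold, the ribosomal S6 kinase RPS6KA2 9.65-fold, TOX2 8.99-fold and ID2 8.26-fold. MYO7B was 4.85-fold lower, IFTAP 4.70-fold, LCT-AS1 4.0-fold, RAG1 3.84-fold and CD1A 3.51-fold. All 36 G2/M genes were lower, 2 by at least 2-fold (excess -0.46), and MYC and ribosome biogenesis genes lay 0.40 below matched lists, both lower than all random lists. The list of genes commonly higher after deacetylase inhibitors lay 0.66 above, with 5 of 18 at least 2-fold higher. Lysosome and autophagy genes lay 0.39 above, both of these higher than all random lists, but the former stayed outside the central 95% under only 7 of 8 alternatives (lowest excess 0.23). ABCA1 had a signal of 721 on the combination and 2028 on the romidepsin array. In all 902 genes were at least 2-fold higher and 128 lower, against 550 and 416 after scaling to a common median and 635 and 235 after quantile normalization.

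Against tamoxifen, the combination array describes romidepsin added to tamoxifen. THY1 was 15.3-fold higher, DLL1 13.8-fold, CSRP2 11.8-fold, ID2 10.7-fold and ABCA1 10.5-fold. THY1 and ABCA1 lay close to the floor on the tamoxifen array, so both ratios are little more than bounds. TRMT2A, a transfer RNA methyltransferase, was 4.5-fold lower, IFTAP 3.96-fold, LCT-AS1 3.68-fold, MRPL54 3.38-fold and ADI1, an enzyme of methionine salvage, 3.24-fold. Cholesterol synthesis and uptake genes lay 0.25 below matched lists (percentile 0.11), with HMGCS1 going from 8951 to 6600. Histone acetyltransferases and bromodomain genes lay 0.34 below (percentile 0.24). G2/M genes lay 0.41 below and were lower in 34 of 36, while fibroblast and cytoskeleton genes lay 0.67 above, with 5 of 15 at least 2-fold higher, but stayed outside the central 95% under only 7 of 8 alternatives (lowest excess 0.18). In all 971 genes were at least 2-fold higher and 130 lower, against 704 and 279 after scaling to a common median.

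The departure from additivity asks whether the combination differed from the product of both single-drug folds. It was 3.27 log2 for ABCA1, where the combination signal of 721 compares with 68.7 under tamoxifen alone, so close to the floor that this departure and the ratio to tamoxifen are little more than bounds. THY1 departed by 2.92, ID2 by 2.84, DENND5A by 2.99 and the potassium channel KCNH2 by 2.69, the last with 1036 on the combination array and 93.1, 151 and 99.4 on the untreated, romidepsin and tamoxifen arrays. THY1 lay close to the floor on the untreated and tamoxifen arrays, so its departure is no firmer than that of ABCA1. On the other side SLC5A5, the sodium-iodide symporter, departed by -2.19, CCT6B by -2.13, IFTAP by -2.06, TRMT2A by -2.01 and EVPL by -1.94, and SLC5A5, CCT6B and EVPL had signals of at most 299 on every array. G2/M genes lay 0.34 below matched lists in this measure, lower than all random lists, and NOTCH pathway genes 0.64 above, the former outside the central 95% under all 8 alternatives and the latter under 7 (lowest excess 0.30). Departures of at least 2-fold numbered 749 upward and 172 downward, 921 in all. Among genes simulated without a change, 512 passed in either direction with noise from the ratios of romidepsin to untreated. With noise from the departures themselves 698 passed, which does not test the departures. Scaling to a common median gave 576 and 274, quantile normalization gave 600 and 265, and 391 of the upward and 50 of the downward ones had an array at the floor.

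The combination array stood alone in 439 genes, 404 of them higher and 35 lower than on all 3 other arrays. The split was 268 and 113 after scaling to a common median and 293 and 63 after quantile normalization, so it is not fixed by these data. RAG1 was among the lower ones, at 2334 against 9277, 8962 and 8381, and IFTAP at 208 against 929, 977 and 823. GSN was among the higher ones, at 407 and at the floor on the other 3 arrays. The untreated array stood alone in 12 genes, the romidepsin array in 8 and the tamoxifen array in 10. For these the combination array has to lie within 1.5-fold of the remaining arrays, so a combination array that deviates lowers their counts. Among genes simulated without a change, the combination array stood alone in 71 and 43, with noise from the departures and from the romidepsin ratios. The other arrays did so in 41 to 67.

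Mean effects of each drug over both levels of the other were tested with limma in the additive fit. Romidepsin went with 13 genes that rose and 0 that fell at a Benjamini-Hochberg adjusted p under 0.05 by limma, where 1204 were higher and 527 lower at an unadjusted p under 0.05. ANXA1 rose 4.75-fold (log2 2.25, SE 0.17, limma adjusted p = 0.00875) and was higher in both pairs of arrays, as were all 13. The residual of the fit is the disagreement between both pairs, so such agreement follows from the selection and is no added support. CSRP2 rose 7.97-fold (limma adjusted p = 0.0210), NPTX2 5.99-fold (0.0210) and CAPN6 4.89-fold (0.0376). CCND2 (limma adjusted p = 0.0412) and CAVIN1 (0.0410) were at the floor only on arrays without romidepsin. Their fitted rises are therefore bounds, at least 7.07-fold for CCND2 and at least 6.61-fold for CAVIN1. PCGF2, GPR65, the kinase scaffold AKAP12, CREG1, ARHGAP29, PLAC8 and CAV1, the main protein of caveolae, rose by mean log2 effects from 1.07 for CAV1 to 2.17 for PCGF2.

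Adjusted over the list alone, 6 of 20 thymocyte and T-ALL transcription factors rose with romidepsin in the limma fit (ETS1, GATA3, HHEX, ID2, ID3 and SOX4), and 5 of 22 thymocyte surface genes rose (CCR7, CCR9, CD69, IL7R and S1PR1), against 0 in either list over all genes. ID2 joins unlike pairs, at 0.59 for romidepsin alone and 3.43 when it was added to tamoxifen. With tamoxifen SOX4 and TOX rose in the first list, and 6 genes rose and 4 fell in the second, CCR9 and CD69 among those called for both drugs, adjusted over the list alone and against 0 over all genes. For romidepsin, likewise adjusted over the list alone, BIK and the death receptor TNFRSF10A rose among 24 pro-apoptotic genes, against 0 over all genes. In the same way CCND2 rose and CDC25A fell with romidepsin among 35 G1/S genes, of which CCND2 alone was called over all genes.

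For tamoxifen 2 genes rose and 1 fell in the limma fit, with 1298 higher and 1031 lower at an unadjusted p under 0.05. ASS1 rose 9.83-fold (log2 3.30, SE 0.24, limma adjusted p = 0.00600) and was higher in both pairs of arrays. The transcription factor KLF2 rose 2.56-fold (limma adjusted p = 0.0413), although its other probe set did not move in that direction. WAC-AS1, an antisense transcript, fell 2.31-fold (limma adjusted p = 0.0335), from 5153 to 2304 without and from 5146 to 2165 with romidepsin.

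Adjusted over the list alone, 19 of 36 G2/M genes fell with tamoxifen, AURKA, AURKB, CCNB1, MKI67 and PLK1 among them, and 0 rose, against 0 over all genes, while for romidepsin 0 of the 36 were called either way, a contrast between the drugs that was not tested. No adjustment was made across lists, and genes of a list can vary together, so these calls are not separate results. Both mean effects on G2/M genes join unlike pairs. The median log2 ratio of these genes was -0.17 for tamoxifen alone and -0.58 when it was added to romidepsin, and for romidepsin -0.11 alone and -0.49 when it was added to tamoxifen. In MYC and ribosome biogenesis 11 of 25 fell and MXD1 rose, and in glycolysis and hypoxia 10 of 26 fell and 4 rose, each adjusted over the list alone and against 0 over all genes. Adjusted over the list alone, against 0 over all genes, of 7 LXR targets ABCA1, ABCG1 and MYLIP fell and NPC2, a lysosomal cholesterol carrier, rose. In the same way, adjusted over the list alone and against 0 over all genes, of 27 cholesterol synthesis and uptake genes HMGCS1, INSIG1 and TM7SF2 rose and ACACA fell. In the stress list 5 of 32 rose, namely ASNS, CEBPB, DNAJB9, EDEM1 and VLDLR, again adjusted over the list alone and with 0 called over all genes. The counts of this fit moved strongly with its settings: romidepsin and tamoxifen had 0 calls each without the mean-variance trend or with scaling on control probe sets, and 768 and 1204 when only genes above the floor on all 4 arrays were tested.

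The ratio of romidepsin to untreated and that of the combination to tamoxifen share no array. Across 12981 genes, which are not independent replicates, they correlated with Pearson's r of 0.413 (bootstrap over genes 0.392 to 0.434) and Spearman's rho of 0.363. Of the 181 genes at least 2-fold higher with romidepsin alone 123 were also 2-fold higher when it was added to tamoxifen, where independent lists would share 13.5, and CSRP2, NPTX2 and ANXA1 were among them. Of the 49 lower genes 1 was lower in both, and 22 had the same sign. For tamoxifen without and with romidepsin r was 0.353 (0.336 to 0.372) and rho 0.389, with 41 of 122 higher genes shared (8.48 if independent), ASS1 among them, and 6 of 51 lower genes shared. The expected counts leave out that dim genes vary more in every comparison.

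**Figure D4:**
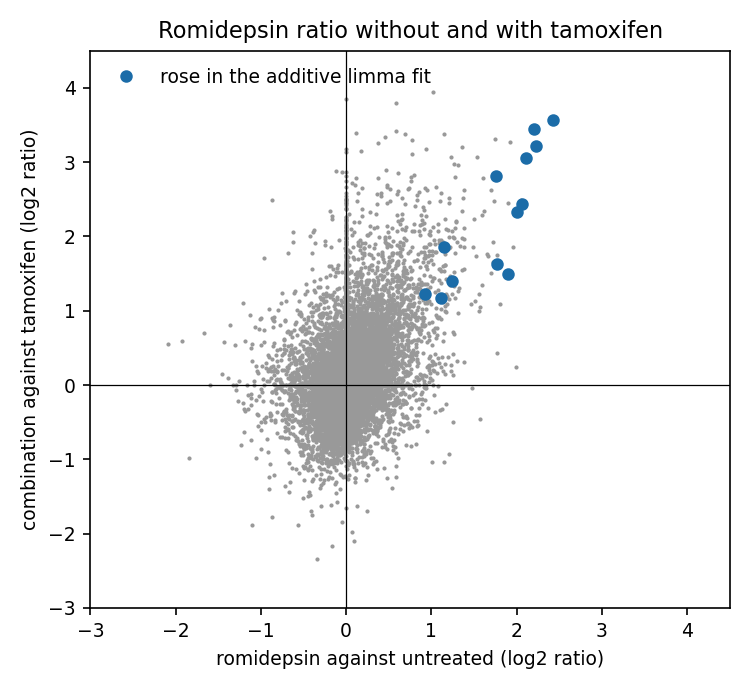
Log2 ratio of romidepsin to untreated (x axis) against log2 ratio of the combination to tamoxifen (y axis), 1 point per measured gene, with the 13 genes called by limma in blue. The 13 called genes lie above 0 on both axes, which follows from their selection by the fit, and Pearson's r over all 12981 genes is 0.413.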

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

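The tests of the signal distribution, of dim genes and of genes bright on the other 3 arrays below were chosen after the result was seen, and the tests of noise and of genes with a mean signal above 500 before it, although the last restriction was itself added once the data had been examined.

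Some genes had ratios of opposite sign, at least 2-fold each, for 1 drug without and with the other, a difference that was not tested because each ratio rests on single arrays. For GAS6 the tamoxifen ratio was -1.06 alone and 1.01 with romidepsin, a difference of 2.07 log2. For SLC5A5 the romidepsin ratio was 1.15 alone and -1.03 with tamoxifen, a difference of -2.19 log2. Both genes are dim, with signals from 81.7 for SLC5A5 to 282 for GAS6.

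Among the 6257 measured probe sets without a single gene name, which no comparison above uses, the combination array stood alone in 116. The untreated array stood alone in 12, the romidepsin array in 1 and the tamoxifen array in 5.

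The number of genes in which the combination array stood alone, 439 against at most 12 for any other array, was weighed further. A combination array that deviates itself lowers the counts of the others, so these counts are no measure of chance. Random noise of that array as the whole cause is argued against, since a second probe set deviated by 1.5-fold in the same direction for 61.5% of these genes (120 of 195), against 14.8% of all genes. The latter share is not matched on brightness, and 161 of the 195 had a mean signal up to 500. For these the contrast was smaller, 59.6% against 25.7%, and noise is less clearly argued against. A different signal distribution as the whole cause is argued against as well, since after quantile normalization the count was 356 against at most 15 on another array. Among genes with a mean signal above 500 the count was 64 against at most 1, but 26 of these were lower, which raised background does not produce, and the mean takes in the combination array. Where the other 3 arrays alone had a mean above 500, 24 genes were higher on the combination array, against at most 1 on another array, and raised background is argued against for these genes. Most of the 404 higher genes are dimmer. For genes with a mean signal up to 500 the second probe set agreed in 59.6% (96 of 161) against 25.7% of all genes of that brightness, so background and a change in expression cannot be told apart there, because a background shared by probe sets could repeat too. A response to both drugs together stays open as a hypothesis, and a difference in the culture or hybridisation of that single array is confounded with its treatment.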

How the results depend on the processing

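No paired analysis was possible because each group has 1 array, so that a replicate number pairs nothing, and the pairs of the additive fit are arrays with and without a drug rather than paired replicates. Leaving out an array was not possible either, as the additive fit would keep no residual degrees of freedom. Genes were called by size, so counts shift with any threshold, and signal over background limits them: a lower floor lets in values within noise, and a higher floor shrinks every ratio of a dim gene. For other settings the cause was not tested. Values are given in the order romidepsin, tamoxifen and combination against untreated, combination against romidepsin, combination against tamoxifen, and departure from additivity. With the floor at the 25th percentile the counts of 2-fold genes were 2095, 2036, 3654, 3009, 3103 and 3800, and with the floor at the 65th percentile 45, 38, 897, 505, 530 and 359. A threshold of 1.5-fold gave 1016, 1089, 3930, 3076, 2940 and 2732, and a threshold of 4-fold gave 8, 4, 288, 115, 185 and 110. Among genes with a mean signal above 500, a restriction added once the data had been examined, they were 26, 24, 503, 210, 230 and 104. With genes above the floor on all arrays compared, likewise added afterwards, romidepsin had 144, tamoxifen 114 and the departure 480. With log2 of signal plus the floor value romidepsin had 143. The combination array stood alone in 261 genes with the floor at the 65th percentile and in 64 with a mean signal above 500, of which 38 were higher and 26 lower, against 404 and 35 as reported.

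Calls by limma for romidepsin and tamoxifen, 13 and 3 as reported, were 3 and 1 with a common median, 0 and 1 with quantile normalization, 0 and 0 with scaling on control probe sets, 0 and 1 with the median over probe sets and 0 and 0 without the trend. The robust fit gave 1 call for tamoxifen, and an adjusted p under 0.1 gave 65 and 19. The counts were 825 and 1097 with the floor at the 25th percentile, 277 and 550 at the 65th, 714 and 956 with log2 of signal plus the floor value, and 768 and 1204 with genes above the floor on all 4 arrays. The cause was not tested, and these counts are no firmer than the reported ones.

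The correlation of the ratios without and with the other drug was, for romidepsin and tamoxifen, 0.182 and 0.111 with the floor at the 25th percentile, 0.471 and 0.467 at the 65th, 0.386 and 0.325 with log2 of signal plus the floor value, and 0.466 and 0.444 with genes above the floor on all 4 arrays. For tamoxifen it was 0.376 with a common median and 0.327 with quantile normalization.

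Lists that changed sign against matched lists were metallothioneins with romidepsin (-0.11 with probe sets of the plain suffix), pro-apoptotic genes on the combination array against untreated (-0.016) and against romidepsin (-0.0074) with the median over probe sets, and estrogen receptors and targets in the departure (-0.13 and -0.076 with the floors at the 25th and 65th percentile, -0.040 with log2 of signal plus the floor value, -0.070 with the plain suffix). Of 240 pairs of a list and a comparison 91 lay outside the central 95% as reported, and 39 did so under all 8 alternatives. Lists of unrelated genes would give 12. Members of a list can vary together, some lists share genes and the comparisons share arrays, so 12 is no measure of chance here. Over 165 pairs of a named gene and a comparison, 923 values under an alternative stayed within the spread of probe sets, 221 moved beyond it, 0 changed sign and 11 could not be computed.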

Other observations

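The tests of LXR targets below were chosen after the result was seen, and that of G2/M genes before it.

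Metallothioneins, small metal-binding proteins, lay 0.56 log2 above matched lists on the combination array against untreated (percentile 98.1, outside the central 95% under 6 of 8 alternatives), with all 6 measured members higher and 2 of them at least 2-fold. Adjusted over the list alone, MT1H, MT1X and MT2A rose with romidepsin and MT3 with tamoxifen in the limma fit, against 0 over all genes. For romidepsin alone the excess of this list was -0.11 with probe sets of the plain suffix. Cytosolic ribosomal protein genes were higher in 27 of 29 members, none by 2-fold, and lay 0.28 above lists of their brightness (6 of 8 alternatives). Among 17 NOTCH pathway genes DLL1, HES1, HES4, HEY1 and JAG1 rose with romidepsin and NOTCH1 fell, and DTX1 fell with tamoxifen, adjusted over the list alone and with 0 called over all genes. For romidepsin this list joins unlike pairs. Its median log2 ratio was 0.10 for romidepsin alone and 0.57 when romidepsin was added to tamoxifen. Among 16 genes of antigen presentation HLA-B, HLA-C, HLA-DMA, HLA-E and HLA-G rose with romidepsin, and HLA-B, HLA-DMA, HLA-E and HLA-G with tamoxifen, again adjusted over the list alone with 0 over all genes. Here too the pairs are unlike. The list median was 0.11 log2 for romidepsin alone and 0.46 when it was added to tamoxifen. For tamoxifen it was 0.07 alone and 0.37 when added to romidepsin. For romidepsin alone the antigen presentation list stayed outside the central 95% under only 4 of 8 alternatives, with a lowest excess of 0. Whether the called HLA and metallothionein genes rest on probe sets open to cross-hybridisation was not examined gene by gene.

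Markers of other cell types were not raised in common on the combination array against untreated. B-cell markers lay at percentile 17.8, myeloid markers at 30.3, erythroid and megakaryocyte markers at 59.4 and epithelial genes at 92.4 of matched lists, while neuronal genes lay at 99.45 and fibroblast and cytoskeleton genes above all random lists. Of the fibroblast and cytoskeleton list ANXA1, COL1A1, S100A10, SPARC, THY1 and TPM1 rose with romidepsin adjusted over the list alone, ANXA1 also over all genes. Histone deacetylases lay at percentile 76.5, drug transporters at 71.7, histone genes at 72.9, anti-apoptotic genes at 30.1, polyamine metabolism at 42.9, DNA methylation and Polycomb genes at 44.9, the oxidative stress response at 26.2, heat shock proteins at 43.2, NF-kB and immediate early genes at 85.3, p53 target genes at 94.0 and germline and cancer-testis genes at 93.1.

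ABCA1, ABCG1 and MYLIP were lower on the tamoxifen array. A faulty probe set is argued against, since 100% of their 10 probe sets above the floor on the untreated array were at least 2-fold lower. Lower activity of LXR on its targets stays open, since the other 4 measured members of the list had a median of -0.24 log2 at percentile 4.72, and too few members are left to decide. Less sterol in the cell may account for it as a hypothesis, since genes of cholesterol synthesis and uptake lay at percentile 100 of matched lists, as this explanation needs. Where tamoxifen was added to romidepsin, the LXR list again lay low (excess -0.49, percentile 0.635). There the synthesis and uptake genes lay only at percentile 66.0 (excess 0.04), and in the departure from additivity at percentile 0.13 (excess -0.21). What the explanation needs was thus seen for tamoxifen alone but not in that pair. The doses are not given in the sources used here, and sterols were not measured here.

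G2/M genes were lower on the combination array. A general loss of signal in bright genes is argued against as the whole cause. The list median was -0.67 log2, and that of lists of the same brightness -0.14. The excess of -0.53 is the value already reported for this list, so this is no separate test. Slower division of cells exposed to both drugs stays open as a hypothesis, a difference in the culture of that single array is confounded with its treatment, and cell numbers and cycle phases were not analysed here.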
